A study of Mus musculus with 4 samples.

How the data were processed

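Colon of C57BL/6 mice at postnatal day 21 was profiled in 4 libraries, 2 from wild-type mice and 2 from Esr2-KO mice, as the labels give them. The design text of the series speaks of triplicates, so that a further library of each genotype may exist that is not among these, and every value here rests on n = 2 per group. Per the labels' protocols, RNA was extracted with Trizol, depleted of ribosomal RNA and made into libraries with a directional NEBNext Ultra kit. The deposited values are counts per gene symbol, whole numbers with no normalization, as the values themselves show. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10. The counting program, the annotation, the use of strand and any filter are not given in the sources used here, so that reads of overlapping, antisense or near-identical genes cannot be told apart. The table held 46095 symbols, of which 20580 had no count in any library and 90.0% matched a RefSeq gene of GRCm38.p6, the same build, which gave the coordinates (counted from 1). The labels do not say whether the libraries of a group came from separate animals. The p-values therefore measure the spread between these libraries, which need not be the spread between animals.

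Library totals were 33709643, 33329655, 32986548 and 30826790 counts, and 3 counts, the floor used for a count of 0, correspond to 0.0826 to 0.114 CPM. Counts of the WT libraries differed by far more than sampling noise, with a chi-square of 39.7 per degree of freedom over 18545 genes, and those of the Esr2-KO libraries by 478. Genes were kept with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 17169. They were scaled by TMM, with factors of 1.08, 1.04, 1.04 and 0.856, and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest, two-sided). Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no fold minimum, and 2 residual degrees of freedom. The common biological coefficient of variation was 0.233. CPM values use the TMM-scaled totals. Standard errors were derived from the F statistic and the coefficient, and an exact counting interval of a ratio was given where a group held 1 to 3 counts.

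Before the data were examined, 36 gene lists were fixed: inflammasome, autophagy, mTOR, lysosome, steroid receptor signalling, inflammatory mediators, interferon-stimulated genes, MHC class II, epithelial defence, goblet cells, colonocytes, crypt stem, proliferation, junctions, enteroendocrine, tuft, B and plasma cells, T and NK cells, myeloid cells, smooth muscle, enteric neurons and glia, stroma, endothelium, adipocytes, other tissues, small intestine, gut position, lipid oxidation, cholesterol synthesis, unfolded protein response, circadian clock, immediate-early genes, mitochondrially encoded genes, ribosomal proteins, neighbours of Esr2 and sex-linked genes. Per list, members past the threshold were counted over all genes and adjusted over the list alone. Camera (limma 3.58.1, on voom values, preset correlation 0.01, two-sided) tested each list against the other genes, adjusted over the 36 lists, and was repeated with an estimated correlation and beside fry. Lists of pancreatic enzymes, of islet genes and of both arms of the clock were written after the data were seen. The list called pancreatic enzymes also took in other genes of the exocrine pancreas, such as Spink1 and Sycn. Bootstrap intervals over genes came from 10000 draws.

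The genes named were set by a rule. It takes Esr2, Nlrp6 and Esr1, the 12 largest rises and 12 largest falls past the threshold with a mean of at least 2 log2 CPM and no overlap of the groups, predicted genes left out, up to 4 members past the threshold of each list or otherwise up to 2 with the smallest p, and the most abundant gene of each library. Car1, Ms4a10, Scnn1a, Scnn1b, Acaa1b, Tph1, Mcm2, Insl5, Pyy, Isl1, Jchain, Hbb-bs, Nts among the hormones, Hoxb7, Cdx2, Bhlhe40, Usp2, Npas2 and Arntl were named beyond it, after their values were seen, to complete small counts or to show members that differ from their list. Some genes that the rule takes are not reported here.

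Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no low-count filter or 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom and edgeR's likelihood ratio test in place of the main test, the replicate number as a block, each library left out in turn, the 50 most abundant genes or the mitochondrial genes left out, and other thresholds. DESeq2 was run on all genes with a count, not on those that filterByExpr kept. Leaving out the pancreatic enzyme genes was added after the data were seen. The procedure was tested on simulated counts with the means and totals of these libraries over 16878 genes. Of 100 genes changed 2-fold 48% were called, of 100 changed 4-fold 83%, and 18 of 162 calls were unchanged genes (11.1%). A simulated list of 30 genes, all raised 2-fold, gave a camera adjusted p of 5.54e-38 with the preset correlation and 0.164 with an estimated one. Of 36 unchanged lists 1 passed with the preset correlation. The simulated genes varied independently, while the correlations estimated for the lists in the data ran from -0.0725 to 0.845. The simulation therefore gives no rate of false passes for correlated lists. A split of 2 against 2 libraries allows too few regroupings to be tested.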

Results

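The data are total RNA profiles of colon from C57BL/6 mice at postnatal day 21, with 2 libraries labelled wild type (WT) and 2 labelled Esr2-KO, for loss of Esr2, the gene of estrogen receptor β. The deposited values were counts per gene symbol, and the 4 libraries held 33709643, 33329655, 32986548 and 30826790 counts (WT 1, WT 2, Esr2-KO 1 and Esr2-KO 2). COX1, a mitochondrial subunit of the respiratory chain, was the most abundant transcript in WT 1, WT 2 and Esr2-KO 1, with 4.79%, 5.69% and 4.66% of the counts (95% Wilson intervals 4.79 to 4.80, 5.68 to 5.70 and 4.65 to 4.66). In Esr2-KO 2 the most abundant transcript was Cela2a, a digestive elastase of the pancreas, with 3.74% (3.73 to 3.74). Together, genes of pancreatic digestive enzymes took 21.2% of the counts of Esr2-KO 2 (21.16 to 21.19), against 0.0504%, 0.0551% and 0.196% in WT 1, WT 2 and Esr2-KO 1. These intervals cover counting error only. Xist had at most 1 count in any library and the Y-linked gene Ddx3y had 1739, 1575, 1224 and 890 counts, so that all 4 libraries carried Y-linked transcripts.

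The targeted gene was examined first. Esr2 lies on chromosome 12 from 76120419 to 76177259 (GRCm38) and had 21 and 13 counts in the WT libraries and 6 and 16 in the Esr2-KO libraries. Its log2 fold change was -0.32 ± 0.78 (SE, n = 2 per group), with an adjusted p of 0.854 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These counts cover the whole gene, the deleted part is not given in the sources used here, and a difference was not detectable at this depth, so that the counts neither checked nor contradicted the genotype labels. The direction turned without WT 1 (log2 fold change 0.04) and without Esr2-KO 1 (0.35). Esr1, which encodes estrogen receptor α, stood at 2.26 and 5.58 CPM, counts scaled by the library total, in WT and 4.21 and 4.74 CPM in Esr2-KO, a log2 fold change of 0.19 ± 0.44 with an edgeR adjusted p of 0.844, and turned to -0.32 without WT 1.

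The comparison of Esr2-KO with WT colon asks what loss of the receptor does to transcripts of the colon, and the series title draws attention to NLRP6 and autophagy. Colon of Esr2-KO mice held less mRNA of the neuropeptide neurotensin (Nts, -7.52 ± 1.16), the proline-rich acidic protein Prap1 (-5.91 ± 0.81), the sulfate transporter Slc13a1 (-4.84 ± 0.60) and the peptide transporter Slc15a2 (-4.81 ± 0.60). None of these 4 falls passed with limma-voom, where the adjusted p was 0.297, 0.182, 0.0521 and 0.0924 and the direction was the same. Esr2-KO colon held more mRNA of the posterior homeobox gene Hoxd12 (5.04 ± 0.46), the clock-associated repressor Ciart (4.41 ± 0.36), the chitinase Chit1 (4.34 ± 0.66) and the connexin Gjb5 (2.85 ± 0.44). Values after ± are standard errors of the log2 fold change, with n = 2 per group. The labels give neither the position within the colon nor the hour of collection. Differences of the groups in either cannot be told apart from loss of Esr2, for these genes and those that follow. Of 17169 genes tested, 462 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 223 higher and 239 lower in Esr2-KO, and 328 of them changed at least 2-fold. In all 462 both Esr2-KO libraries lay on the same side of both WT libraries, as they did for 54.7% of all tested genes, where chance gives 33.3%. The count was 165 without WT 1, of which 111 were among the 462, and 1804 without Esr2-KO 1. It was 501 without Esr2-KO 2, the library with pancreatic transcripts, and 364 of the 462 were among those.

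The other genes with the largest rises included Mettl7a3 (3.86 ± 0.58), Ly6g (2.97 ± 0.54), the glycosyltransferase B3gnt7 (2.75 ± 0.32), the thyroid hormone carrier transthyretin (Ttr, 2.52 ± 0.31) and Hoxb13 (2.51 ± 0.34). Itih2 (2.47 ± 0.39), the cardiac troponin T gene Tnnt2 (2.40 ± 0.33) and the folate transporter Slc46a1 (2.37 ± 0.37) followed. B3gnt7 stood at 76.5 and 147 CPM in WT and at 708 and 799 CPM in Esr2-KO, and Hoxb13 at 72.8 and 153 against 616 and 676 CPM. The largest falls also took in Hoxb8 (-5.51 ± 0.78), the glucuronosyltransferase Ugt2b5 (-4.88 ± 0.81), the mucin core glycosyltransferase B3gnt6 (-4.56 ± 0.62), Tmem252 (-4.44 ± 0.32), and the retinol esterifying enzyme Lrat (-4.05 ± 0.56). Igkv4-57 (-4.12 ± 0.75), the cytochrome Cyp2c65 (-3.87 ± 0.66) and the carboxylesterase Ces1g (-3.74 ± 0.42) completed them. B3gnt6 fell from 78.2 and 57.1 CPM to 4.68 and 0.91 CPM, and Cyp2c65 from 157 and 267 to 23.5 and 5.31 CPM. Adjusted p values of these 24 genes ran from 0.0117 for Tmem252 to 0.0461 for Ly6g by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mettl7a3, Ly6g, Ugt2b5, Cyp2c65, Ces1g and Igkv4-57 belong to families of near-identical genes whose reads the counting could have split, so their values are uncertain. Hoxb8 did not pass with limma-voom (adjusted p = 0.138), Ly6g with upper-quartile factors (0.0505) or Igkv4-57 with the replicate number as a block (0.0657). Tnnt2, Ugt2b5, B3gnt6, Igkv4-57, Lrat and Cyp2c65 did not pass without WT 1, nor Tnnt2, Ugt2b5, Lrat and Cyp2c65 without WT 2.

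Nlrp6, a sensor of the innate immune system named in the series title (chromosome 7, 140920902 to 140929192), did not differ detectably. It stood at 189 and 248 CPM in WT and 188 and 227 CPM in Esr2-KO, a log2 fold change of -0.07 ± 0.18 with an edgeR adjusted p of 0.849, and turned to 0.16 without WT 2 and 0.06 without Esr2-KO 1. Among 20 tested inflammasome genes 1 rose and none fell, namely Il18, the interleukin released by inflammasomes (1.08 ± 0.16, 72.1 and 96.8 against 182 and 175 CPM). Adjusted over the list alone, 3 were higher and 0 lower, while 15 of the 20 had negative log2 fold changes, the list median was -0.19 and the direction in camera was negative. In the autophagy list 1 of 46 genes rose, the mitophagy receptor Bnip3 (1.11 ± 0.17), and the median of the list was 0.03. Adjusted over the list alone, 4 autophagy genes were higher and 4 lower. Prkaa1, a catalytic subunit of AMP-activated kinase (-0.73 ± 0.14), was the gene past the threshold among 28 of the mTOR pathway (median 0.06), and the list of 28 lysosomal genes had a median of 0.09. None of these 4 lists passed camera, limma's competitive gene set test (adjusted p = 0.296, 0.775, 0.936 and 0.0528), while the lysosomal list passed without WT 2 (0.00311, median 0.18), with the replicate number as a block (0.0481) and without pancreatic enzyme genes (0.0491). The call of Bnip3 and of Prkaa1 ended without WT 1 or without WT 2, that of Prkaa1 also without Esr2-KO 2, and that of Il18 without WT 1.

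Of 21 tested genes of steroid receptor signalling 2 rose, the coactivator Ncoa3 (0.62 ± 0.11) and the estrogen sulfotransferase Sult1e1, and the list had a median of 0.20 (camera adjusted p = 0.0689, and 0.0359 without WT 2 and 0.0243 without Esr2-KO 1). Adjusted over the list alone, 5 of its genes were higher and 1 lower. Sult1e1 had 0 and 1 counts in WT and 61 and 74 in Esr2-KO, a ratio of 158 with a 95% counting interval from 28.0 to 6306. Ncoa3 did not pass without Esr2-KO 2 or without WT 1 or without WT 2, nor Sult1e1 without WT 1. Of 18 tested neighbours of Esr2 on chromosome 12, none passed over all genes, and the list had a median of 0.09 (camera adjusted p = 0.480). Adjusted over the list alone, 1 was higher and 0 lower. Its smallest p values belonged to Max (0.70 ± 0.14, edgeR adjusted p = 0.0576) and Plekhg3 (0.29 ± 0.14, edgeR adjusted p = 0.293).

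Genes of cell division were lower on balance as a list, with a median of -0.85 over 30 tested (camera adjusted p = 1.28e-11, and 0.760 with an estimated correlation). Over all genes 1 of the 30 passed, the mitotic kinesin Kif11 (-1.30 ± 0.23), and adjusted over the list alone 23 were lower and 0 higher. The fitted log2 fold change was negative for all 30, but Mcm2, a helicase subunit of DNA replication, was at -0.15 ± 0.23, with 36.4 and 24.3 CPM in WT and 23.7 and 31.1 CPM in Esr2-KO. Kif11 did not pass without WT 1.

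Of 22 tested enteroendocrine genes 6 fell and 0 rose, with a list median of -0.49 (camera adjusted p = 0.0110, and 0.760 with an estimated correlation). Those that fell were proglucagon (Gcg, -1.59 ± 0.18), cholecystokinin (Cck, -3.16 ± 0.36), somatostatin (Sst, -1.46 ± 0.22), the prohormone convertase Pcsk1 (-1.87 ± 0.25), Tph1 of serotonin synthesis and Nts. Adjusted over the list alone 11 were lower and 3 higher, the latter the hormone genes Insl5 (0.63 ± 0.13) and Pyy (0.46 ± 0.12) and the transcription factor gene Isl1 (1.14 ± 0.36), with edgeR adjusted p values over all genes of 0.0556, 0.102 and 0.146. Gcg stood at 150 and 112 CPM in WT and 47.6 and 39.3 CPM in Esr2-KO. Cck and Pcsk1 did not pass without WT 1, nor Sst without WT 2. Tuft cell genes were lower on balance as a list, with a median of -0.64 (camera adjusted p = 0.00183, and 0.760 with an estimated correlation), while none of its 16 genes passed over all genes. Dclk1 (-0.82 ± 0.18, edgeR adjusted p = 0.0714) and Trpm5 (-1.57 ± 0.36, edgeR adjusted p = 0.0758) came closest. Of the 16, 5 were lower and 0 higher when adjusted over the list alone.

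In the goblet cell list B3gnt6 fell and 19 of 20 genes did not pass over all genes, with a list median of -0.50 (camera adjusted p = 0.0223, and 0.760 with an estimated correlation). When adjusted over the list alone, 6 of the goblet cell genes were lower and 1 higher. The list median against the WT mean was -0.08 in Esr2-KO 1 and -1.02 in Esr2-KO 2, and the list did not pass without Esr2-KO 2 (adjusted p = 0.0647). Absorptive colonocyte genes went both ways, with 4 of 28 higher and 4 lower and a median of 0.10 (camera adjusted p = 0.936). The lower ones included the cytochrome Cyp2c55 (-2.69 ± 0.21), from 2086 and 2260 to 336 and 335 CPM, uroguanylin (Guca2b, -1.22 ± 0.20) and carbonic anhydrase Car1 (-2.11 ± 0.39). The higher ones were Saa1, Ms4a10 (2.45 ± 0.43) and the epithelial sodium channel subunits Scnn1a (0.71 ± 0.13) and Scnn1b (1.20 ± 0.22). When adjusted over the list alone, 11 of the 28 colonocyte genes were higher and 12 lower. Among 19 crypt stem and Wnt target genes Cd44 fell (-0.91 ± 0.14) and Smoc2 rose (0.64 ± 0.12), with a list median of 0.12 (camera adjusted p = 0.563). None of 22 junction genes passed (median 0.15, camera adjusted p = 0.111), and Cldn15 (-1.41 ± 0.29, edgeR adjusted p = 0.0600) and Cldn23 (-0.54 ± 0.14, edgeR adjusted p = 0.0929) had the smallest p values. Guca2b, Cd44 and Smoc2 did not pass without WT 1 or without WT 2, nor Smoc2 without Esr2-KO 2.

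Of 16 tested genes of small intestinal enterocytes and Paneth cells 12 were negative, with a list median of -1.27 (camera adjusted p = 0.00647, and 0.760 with an estimated correlation). None passed over all genes, while adjusted over the list alone 9 were lower and 2 higher. Fabp1, a fatty acid binding protein, had 17 and 40 counts in WT and 0 in both Esr2-KO libraries, at least 16.2-fold lower against a floor of 3 counts over the group, with an edgeR adjusted p of 0.0621, and Slc5a1 had a log2 fold change of 0.75 ± 0.15 (edgeR adjusted p = 0.0579). Among 24 genes of fatty acid oxidation, ketogenesis and PPAR targets, Pdk4, a brake on pyruvate oxidation (-2.66 ± 0.17), Pparg (-0.75 ± 0.13) and Acaa1b (-4.06 ± 0.74) were among 4 that fell, and the lipid droplet coat gene Plin2 rose (1.35 ± 0.20). That list had a median of -0.05 (camera adjusted p = 0.0916) and passed without Esr2-KO 2, the library with pancreatic transcripts (adjusted p = 0.00775, median -0.13), and without WT 1 (7.45e-05, median -0.19). Cholesterol synthesis genes had a median of -0.31 (camera adjusted p = 0.0108, and 0.760 with an estimated correlation), with none of 21 past the threshold, and the list did not pass without WT 1 (adjusted p = 0.900). Hmgcs1 (-1.03 ± 0.24, edgeR adjusted p = 0.0837) and Fdps (-0.75 ± 0.25, edgeR adjusted p = 0.165) led it. Plin2 did not pass without WT 1, nor Pparg without WT 1 or without WT 2 or Esr2-KO 2.

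Chemokines of the interferon response were lower. Cxcl10 (-1.76 ± 0.27) and Cxcl9 (-2.99 ± 0.56) fell among 14 tested inflammatory mediators, whose median was -0.88 (camera adjusted p = 0.00268, and 0.760 with an estimated correlation). Of the 14, 6 were lower and 0 higher when adjusted over the list alone. The GTPase Iigp1 (-1.96 ± 0.25) was the 1 of 28 interferon-stimulated genes to pass, with a list median of -0.49 (camera adjusted p = 1.19e-04, and 0.760 with an estimated correlation). The interferon list had a median of -0.13 in Esr2-KO 1 and -0.94 in Esr2-KO 2 and did not pass without Esr2-KO 2 (adjusted p = 0.161). Among 22 tested epithelial defence genes the serum amyloid gene Saa1 rose (1.55 ± 0.24), and Saa3 (-4.41 ± 0.73) and the dual oxidase maturation factor Duoxa2 (-1.10 ± 0.20) fell, with a list median of -0.17 (camera adjusted p = 0.335, and 0.0136 without WT 1 and 0.0211 without Esr2-KO 1). Saa1 and Saa3 are close relatives, so that their values are uncertain. Each of these calls ended without WT 1, and those of Cxcl9, Cxcl10, Saa3 and Duoxa2 also without WT 2.

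No gene of the lymphocyte lists passed the threshold. Genes of T cells, innate lymphoid and NK cells had a median of -0.91 over 21 tested (camera adjusted p = 1.55e-04, and 0.760 with an estimated correlation), with Gzmb at -1.93 ± 0.40 (edgeR adjusted p = 0.0585) and Gzma at -4.10 ± 1.05 (edgeR adjusted p = 0.0945). B and plasma cell genes had a median of 1.46 over 17 tested (camera adjusted p = 0.0294, and 0.760 with an estimated correlation), with 12 positive and 5 negative. In it Cxcr5 was at 1.61 ± 0.56 (edgeR adjusted p = 0.177), and Jchain, the joining chain of secreted antibodies, at -1.24 ± 0.59 (edgeR adjusted p = 0.298), with -0.53 in Esr2-KO 1 and -2.62 in Esr2-KO 2 against the WT mean. Outside the list, of 47 tested Igkv genes, which encode variable segments of antibody light chains and were examined after the values were seen, 4 fell and 0 rose, with a median of -1.06, and their near-identical sequences leave single members uncertain. The B and plasma cell list did not pass without WT 1 (adjusted p = 0.0892), without Esr2-KO 1 (0.366) or with the replicate number as a block (0.0694). Myeloid genes (median -0.09 over 24, camera adjusted p = 0.362) and MHC class II genes (median -0.07 over 8, camera adjusted p = 0.578, with a mean of 0.48) did not pass. Their leading genes were Ccr2 (-0.72 ± 0.21), Cd68 (0.55 ± 0.17), H2-DMb2 (3.12 ± 0.78) and Ctss (0.53 ± 0.19), with edgeR adjusted p values from 0.0879 to 0.193.

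Genes of enteric neurons and glia were lower on balance, with a median of -0.40 (camera adjusted p = 0.00142, and 0.760 with an estimated correlation), 20 of 22 negative and none past the threshold. Tac1 was at -0.62 ± 0.15 (edgeR adjusted p = 0.0795). Smooth muscle genes did not pass, with a median of -6.5e-04 over 20 (camera adjusted p = 0.775, and 0.0252 without WT 2 and 0.0392 without Esr2-KO 2), Synpo2 at -0.62 ± 0.19 and Mylk at -0.33 ± 0.17. In the list of fibroblasts and matrix tenascin C fell (Tnc, -0.78 ± 0.11) with 23 of 24 not past the threshold, a median of 0.17 and a camera adjusted p of 0.339. Endothelial genes had a median of 0.15 over 17 (camera adjusted p = 0.0689, and 0.0366 without WT 2), with Tie1 at 0.54 ± 0.14 and Egfl7 at 0.36 ± 0.15. Adipocyte genes had a median of -0.41 over 16 (camera adjusted p = 0.0620, and 2.29e-05 without WT 1 and 2.94e-05 without Esr2-KO 1), at 0.24 in Esr2-KO 1 and -1.12 in Esr2-KO 2, and Pparg was the 1 that passed. Tnc did not pass without WT 1.

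**Figure D1:**
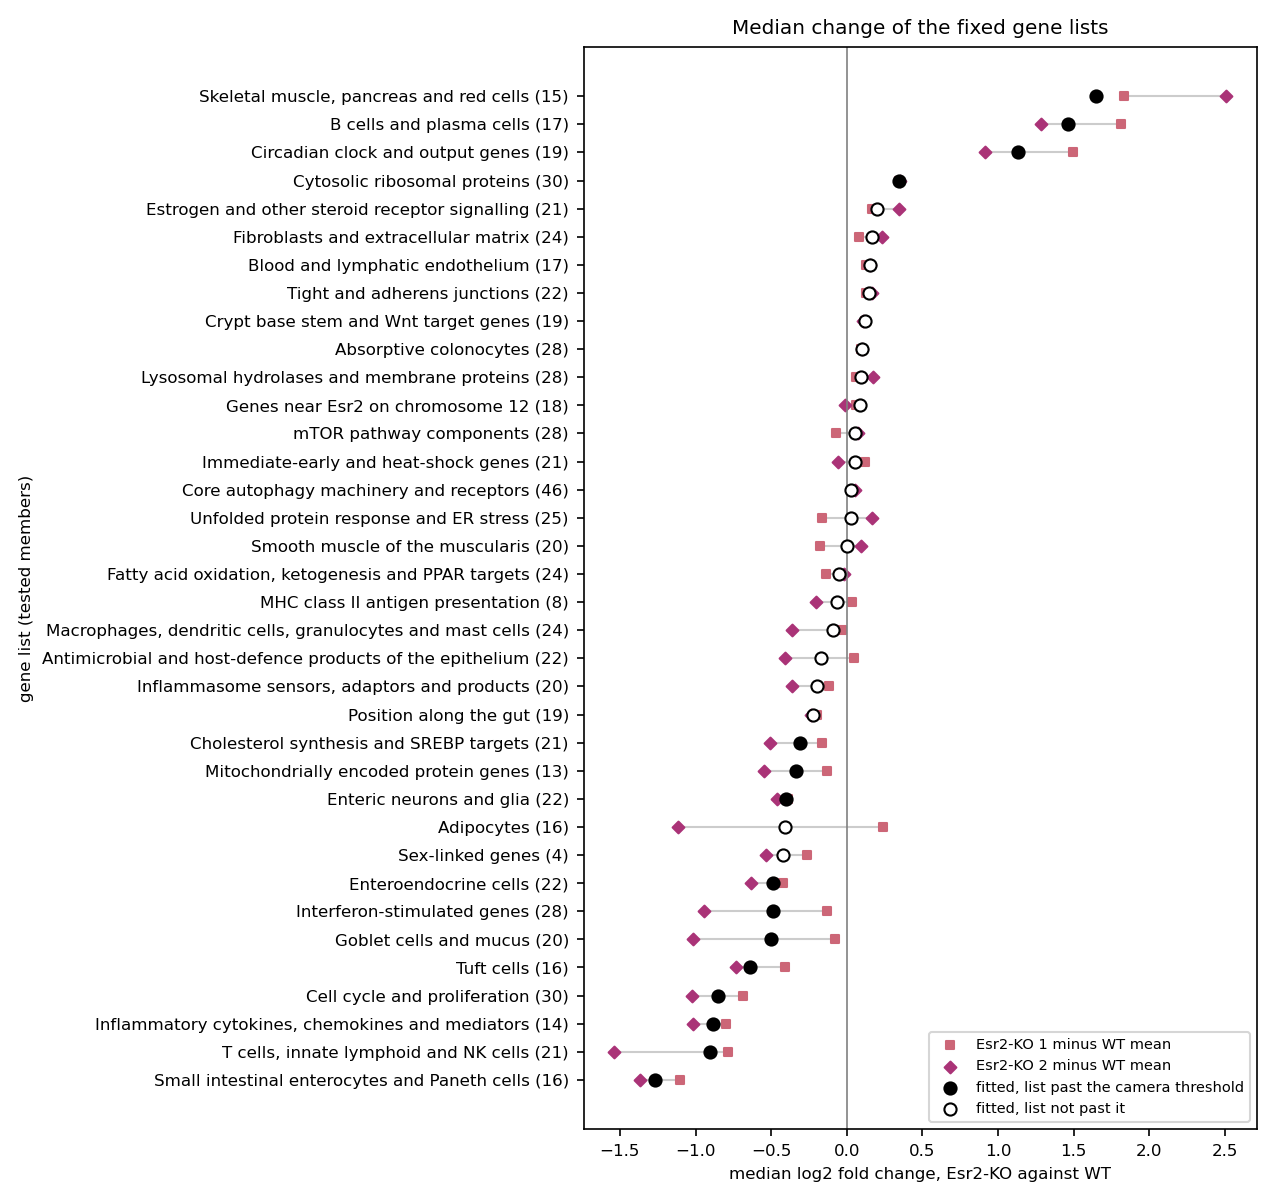
Median log2 fold change of Esr2-KO against WT for each of the 36 gene lists, with the number of tested members in brackets; circles are the fitted values, filled where the list passed camera, and squares and diamonds are each Esr2-KO library against the WT mean. The proliferation list lies at -0.85 and the circadian list at 1.14, while the adipocyte list lies at 0.24 in Esr2-KO 1 and at -1.12 in Esr2-KO 2.

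Genes of the circadian clock differed in both directions. Of 19 tested, 5 rose, namely Ciart, Per2 (2.21 ± 0.18), Per3 (2.31 ± 0.29), Bhlhe40 and Usp2. Another 3 fell, the repressor Nfil3 (-2.64 ± 0.25) together with Npas2 and Arntl, the last of which encodes a partner of CLOCK. Per2 stood at 9.55 and 7.07 CPM in WT and 38.6 and 38.1 CPM in Esr2-KO. The list had a median of 1.14 (camera adjusted p = 1.55e-04, and 0.760 with an estimated correlation). Adjusted over the list alone 11 were higher and 4 lower. Per3 did not pass without WT 1.

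**Figure D2:**
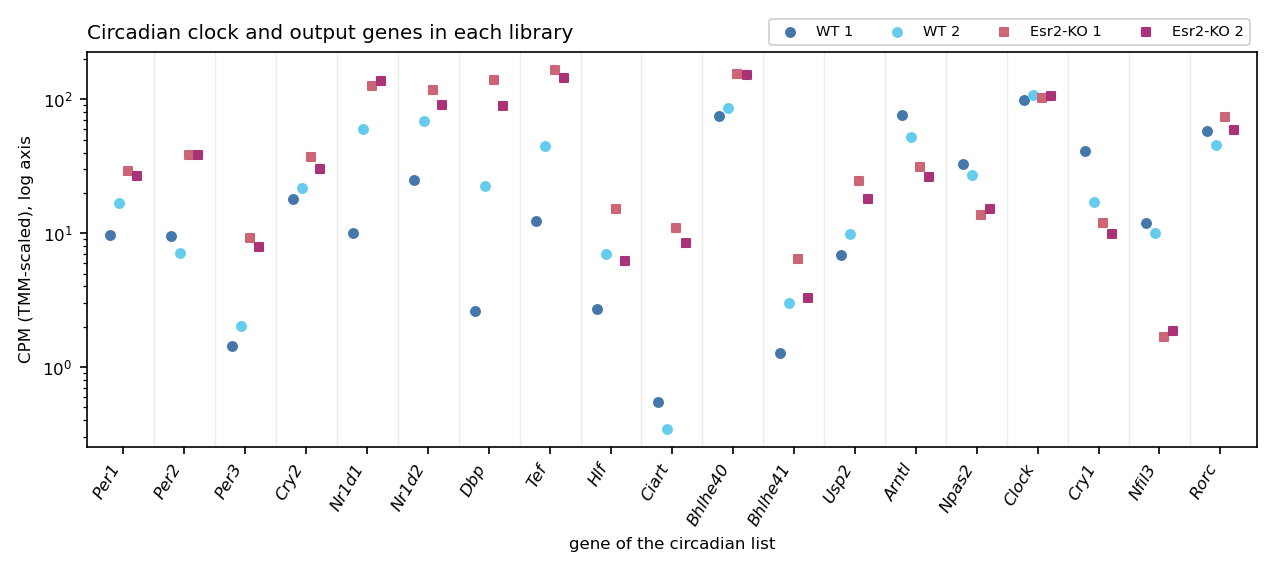
Levels of the 19 circadian genes in CPM on a log axis, with a circle for each WT library and a square for each Esr2-KO library. Per2 lies at 9.55 and 7.07 CPM in WT and at 38.6 and 38.1 CPM in Esr2-KO, and Dbp at 2.64 and 22.3 CPM in WT 1 and WT 2.

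Genes that mark position along the gut also went both ways. Of 19 tested, 2 rose, Hoxd12 and Hoxb13, and 4 fell, Hoxb8, Hoxa11 (-1.26 ± 0.19), Hoxb7 (-3.34 ± 0.59) and the intestinal homeobox gene Cdx2 (-2.03 ± 0.34). The list had a median of -0.23 (camera adjusted p = 0.775). Adjusted over the list alone 6 were higher and 8 lower. Hoxa11 did not pass without WT 1 or without WT 2.

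**Figure D3:**
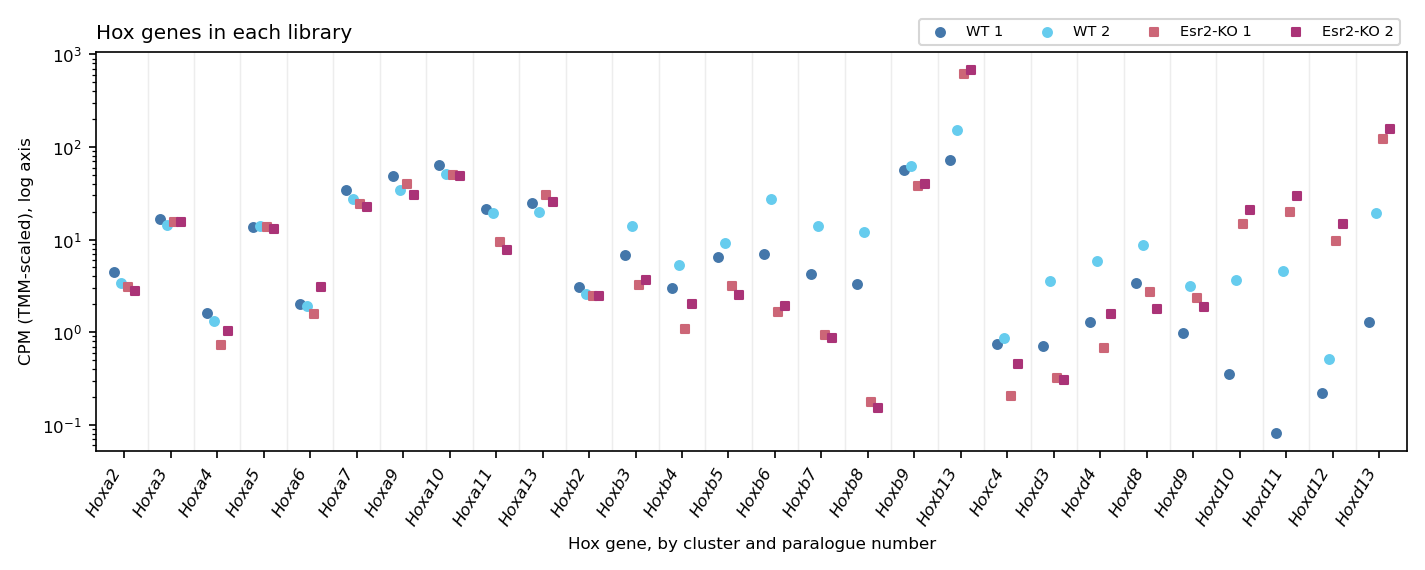
Levels of the 28 tested Hox genes in CPM on a log axis, by cluster and paralogue number, with a circle for each WT library and a square for each Esr2-KO library. Hoxb13 lies at 72.8 and 153 CPM in WT and at 616 and 676 CPM in Esr2-KO, and Hoxb8 at 3.33 and 12.1 against 0.175 and 0.152 CPM.

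Lists that watch tissue handling and RNA quality gave these values. Cytosolic ribosomal protein genes had a median of 0.35, with 28 of 30 positive and none past the threshold (camera adjusted p = 3.28e-08, and 0.760 with an estimated correlation), and Rpl14 stood at 0.43 ± 0.13. Mitochondrially encoded genes had a median of -0.33 over 13 (camera adjusted p = 0.00995, and 0.760 with an estimated correlation), with ATP8 at -0.85 ± 0.40 and ND4L at -0.66 ± 0.34, and did not pass without Esr2-KO 2 (adjusted p = 0.388) or without WT 2 (0.133). These genes took 7.53%, 8.80%, 7.15% and 4.43% of the counts in WT 1, WT 2, Esr2-KO 1 and Esr2-KO 2. The total of Esr2-KO 2 includes the 21.2% from pancreatic enzyme genes, which lowers every other share of that library. Immediate-early and heat-shock genes had a median of 0.06 over 21 (camera adjusted p = 0.398), with Klf2 at 0.65 ± 0.15 and Dnajb1 at 0.36 ± 0.11. Unfolded protein response genes had a median of 0.03 over 25 (camera adjusted p = 0.947), with a negative direction in camera, Herpud1 at 0.82 ± 0.23 and Pdia6 at -0.71 ± 0.21. The 4 tested sex-linked genes had a median of -0.42 (camera adjusted p = 0.0620, and 0.0310 without WT 1 and 0.0244 without Esr2-KO 1).

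Of the markers of tissues outside the colon, pancreatic enzyme genes were uneven between the Esr2-KO libraries. The list of skeletal muscle, pancreas and red cell genes had a median of 1.65 over 15 (camera adjusted p = 0.00464, and 0.760 with an estimated correlation), with none past the threshold. Its median against the WT mean was 1.83 in Esr2-KO 1 and 2.51 in Esr2-KO 2, and the list also passed without Esr2-KO 2 (adjusted p = 1.04e-07, median 1.86). The hemoglobin gene Hbb-bs stood at 8.10, 42.7, 69.2 and 90.1 CPM in WT 1, WT 2, Esr2-KO 1 and Esr2-KO 2 (edgeR adjusted p = 0.219). Without pancreatic enzyme genes the list of other tissues did not pass camera (adjusted p = 0.0635). The carboxypeptidase Cpa1 stood at 3.28, 0.949, 28.0 and 15985 CPM in WT 1, WT 2, Esr2-KO 1 and Esr2-KO 2, and the chymotrypsinogen Ctrb1 at 6.00, 1.84, 45.0 and 22055 CPM, with edgeR adjusted p values of 0.0862 and 0.0872. All lists past camera gave an adjusted p of 0.760 with an estimated correlation, and fry, which tests whether the genes of a list move one way, passed none of the 36.

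**Figure D4:**
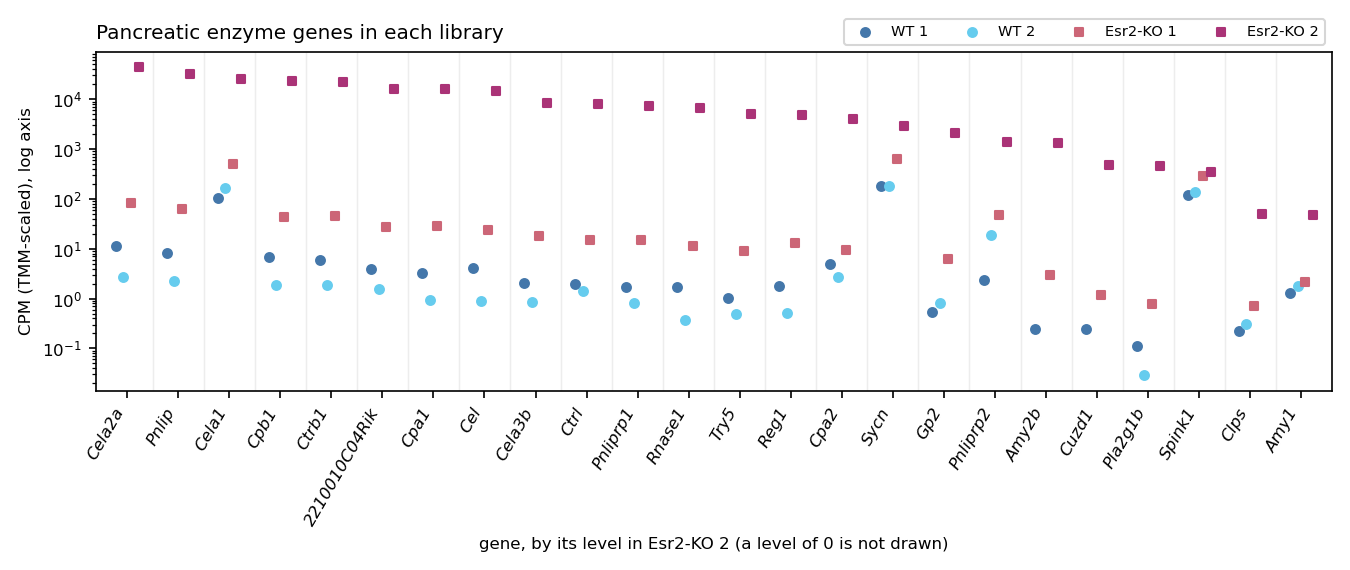
Levels of 24 pancreatic enzyme genes in CPM on a log axis, ordered by their level in Esr2-KO 2, with a circle for each WT library and a square for each Esr2-KO library; levels of 0 are not drawn. Cela2a lies at 43695 CPM in Esr2-KO 2 and at 83.2 CPM in Esr2-KO 1.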

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

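The removal of pancreatic enzyme genes was chosen after the data were seen, and the other settings before. The 462 genes that differed between Esr2-KO and WT kept their direction in every setting in which they were tested. The groups did not overlap in any of the 462, which largely fixes that outcome, so it says little about stability. With library totals only the median gene shifted by -0.16. The number of genes past the threshold was then 695, of which 29.9% were higher against 48.3% with TMM. It was 1916 without a low-count filter, 1693 with DESeq2's Wald test, 1341 with edgeR's likelihood ratio test and 1245 at an adjusted p of 0.1. The DESeq2 run also left out filterByExpr, and 25515 genes entered both settings, but DESeq2 applied its own default filter on mean count before adjustment. Its number therefore does not show the effect of the test alone. With 1 library left out it ranged from 165 without WT 1 to 1804 without Esr2-KO 1, where a lone library is assumed to vary like those of the other group and 1 residual degree of freedom is left. The cause was not tested. The other settings gave 328 to 606, with 589 without the pancreatic enzyme genes. Library totals rescale each library by its own factor, so genes did not all shift alike. The medians of 11 lists that lay little above 0 turned. A shift near the -0.16 of the median gene could give this for most of them, so the turn says little about their stability.

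Esr2 ranged from -1.42 to 0.35 with 1 library left out and turned positive without WT 1 (0.04) and without Esr2-KO 1 (0.35). Nlrp6 ranged from -0.26 to 0.16 and turned positive without WT 2 (0.16) and without Esr2-KO 1 (0.06), and Esr1 turned to -0.32 without WT 1 and reached 1.004 without WT 2. No setting brought Esr2 or Nlrp6 past the threshold. Of the 54 genes past the threshold that the naming rule takes, 26 still passed without WT 1, 37 without WT 2, 54 without Esr2-KO 1 and 50 without Esr2-KO 2. Limma-voom did not pass Nts, Prap1, Hoxb8, Slc13a1, Slc15a2 and Saa3, nor did upper-quartile factors pass Ly6g, Ncoa3, Cxcl9 and Smoc2. Esr2 lay below the filter of 1 CPM in 2 libraries and has no value there.

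With the replicate number as a block 490 genes passed, 343 of them among the 462, and Igkv4-57, Prkaa1, Ncoa3, Saa1, Saa3, Smoc2 and Pparg did not. The deviations of same-numbered libraries from their group means had a correlation of -0.06 across genes. That value gave no sign of pairing, but a single correlation cannot exclude a shared litter, day or batch. The number of lists past camera was 15 with the block and 14 to 18 with 1 library left out, and 10 lists passed in all of these fits. It was 0 by fry and 0 with an estimated correlation, which did not recover a simulated list of raised genes either (camera adjusted p = 0.164). The simulated genes varied independently, so that list does not show which setting is right for correlated lists. With 2 libraries per group the simulation called 48% of genes changed 2-fold, so that smaller changes are often missed.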

Other observations

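Several gene families of xenobiotic and steroid metabolism, picked after their values were seen and not tested for enrichment, held changed genes. Of 13 tested carboxylesterase genes 5 fell and 1 rose in Esr2-KO, with Ces1f at -1.77 ± 0.11 (SE, n = 2 per group) and Ces1d at -1.40 ± 0.15. Of 10 tested glucuronosyltransferase genes 4 fell and 0 rose, among them Ugt1a1 (-3.22 ± 0.48), which conjugates bilirubin. The steroid dehydrogenases Hsd3b2 (-2.05 ± 0.25) and Hsd3b3 (-1.82 ± 0.23) fell. Among cytochromes of the Cyp2d family 3 of 7 rose and 0 fell, and Cyp2d9 stood at 21.1 ± 5.51 CPM (SD, n = 2) in WT and 50.4 ± 10.3 CPM in Esr2-KO. The Cyp2c family went both ways, with 3 of 7 lower and 1 higher and a median of 0.19. Its higher member was Cyp2c68 (2.16 ± 0.36). These families hold near-identical genes, so single members are uncertain.

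Enzymes that build glycans split, with 5 of 37 tested higher and 5 lower. Gcnt3 (-1.86 ± 0.18), which branches mucin glycans, fell with B3gnt6, while B4galnt3 (2.33 ± 0.42) and B3gnt5 (0.99 ± 0.12) rose with B3gnt7. Among 16 interferon-induced GTPases 5 fell, including Gbp6 (-1.85 ± 0.24) and Gbp4 (-1.17 ± 0.19). These genes too were chosen after their values were seen. The goblet cell products Retnlb and Ang4 stood at 617, 1323 and 1112 CPM and at 1763, 2717 and 2374 CPM in WT 1, WT 2 and Esr2-KO 1, and at 2.28 and 4.86 CPM in Esr2-KO 2.

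All tests in the paragraphs that follow were chosen after the results were seen. Pancreatic enzyme transcripts made up 21.2% of the counts of Esr2-KO 2, led by Cela2a (43695 CPM), Pnlip (31807 CPM) and Cela1. Loss of Esr2 is argued against as the cause of that share, since Esr2-KO 1 held a median of 0.208% of the level in Esr2-KO 2 over 24 tested genes (quartiles 0.181 to 0.578). This does not cover Spink1, at 120 and 138 CPM in WT and 285 and 349 CPM in Esr2-KO (edgeR adjusted p = 0.0204). Cela1 stood at 104, 163 and 502 CPM and Sycn at 181, 185 and 642 CPM in WT 1, WT 2 and Esr2-KO 1. Pancreatic tissue or RNA in the sample of Esr2-KO 2 is a candidate explanation: 22 of the 24 were at least 10-fold above every other library there. So were 2 of 8 islet genes by counts, with Ins1 at 154 and Ins2 at 512 there and Ins2 at 6, 0 and 0 in WT 1, WT 2 and Esr2-KO 1. In WT 4 of the 24 had a mean above 10 CPM, of which Pnliprp2 had 2.34 and 19.2 CPM in the 2 libraries. Whether these levels and the trace in Esr2-KO 1 came from colon, from attached tissue or from the other library was not tested.

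Clock genes differed between the genotypes in opposite arms. The arm of Per, Dbp and Nr1d1 had a median of 1.63 and the arm of Arntl -1.14, a difference of 2.77 over all 17 tested genes, as a different hour of collection in the groups could give. Between the WT libraries, which share a genotype, the same difference was 1.30, and against WT it was 3.14 in Esr2-KO 1 and 2.91 in Esr2-KO 2. Pancreatic RNA in Esr2-KO 2 is argued against as the whole cause for these genes. The 3.14 in Esr2-KO 1 (95% bootstrap interval over genes 1.98 to 4.93) lay above the 1.30 between the WT libraries. These genes are not independent replicates, the interval holds no spread between libraries, and the 1.30 has no interval of its own. The labels give no hour, so hour of collection and loss of Esr2 cannot be told apart.

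Hox genes shifted toward the posterior end: 18 of 20 tested genes of paralogues 1 to 9 had negative and 6 of 8 of paralogues 10 to 13 positive log2 fold changes. Across 28 genes, which are not independent replicates, fold change rose with paralogue number (Spearman's rho 0.53, permutation p = 0.0044, Pearson's r 0.54, permutation p = 0.0028), which restates the pattern and does not test its cause. Between the WT libraries rho was 0.19, while Hoxd10 to Hoxd13 and Hoxb13, picked for the pattern, differed there by a median of 3.35 log2 units. In Esr2-KO 1, where pancreatic enzyme genes took 0.196% of the counts, rho was 0.53. Its 95% bootstrap interval over genes ran from 0.17 to 0.77. The interval takes in the 0.19, so a shift of the size seen between the WT libraries was not excluded for Esr2-KO 1. Whether pancreatic RNA in Esr2-KO 2 was the whole cause was therefore not decided. The labels give no position within the colon, so that a different position and loss of Esr2 cannot be told apart.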
